A study of Mus musculus with 10 samples.

How the data were processed

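RNA of 10 mouse spinal cord samples taken at day 14 was sequenced. Per the labels' protocols, RNA was extracted with Trizol, polyadenylated mRNA was captured with poly-T beads, cDNA was made from random primers and paired-end adapter libraries were sequenced on an Illumina NovaSeq. The protocol names no strand-marking step. Per the submitters' processing notes, reads were trimmed with cutadapt and aligned with HISAT2 2.0.5. The read counter, the annotation release and any filter are not given in the sources used here.

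The authors deposited 1 table of 21936 genes with an unnormalised read count and an FPKM value per sample, per the file headers. It has 10 count columns and 10 FPKM columns, 1 of each per sample, and 0 further sample columns. The deposited Length column gives a gene length in bases. The authors' FPKM values equal the count divided by the length in kilobases and by the column total in M reads: of 153986 values above 0.1, 100% lay within 1% of that. The gene coordinates are GRCm38, since 21817 of the 21936 Ensembl identifiers are in the GENCODE M21 annotation of that build and 21617 have the same start and end there.

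Samples were grouped by their titles, 5 as Nar and 5 as EAE, because the treatment field names naringenin for all 10. Sample totals were 14504726 to 18961501 counted reads. The labels do not state whether replicates are separate animals. Each sample was treated as 1 replicate. Samples of a group differed by more than counting noise, which separate libraries of the same RNA can do as well.

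Counts were tested with edgeR 4.0.16 in R 4.3.3: genes were filtered with filterByExpr, which left 14595, scaled with TMM factors and fitted with the quasi-likelihood model (estimateDisp, robust glmQLFit, glmQLFTest), coded Nar minus EAE. P-values are two-sided with Benjamini-Hochberg adjustment over all tested genes, at a threshold of 0.05. Standard errors are the size of the log2 fold change divided by the square root of the F statistic. CPM values use the TMM-scaled totals, and log2 CPM adds a prior count of 2. Single values per sample were compared with a two-sided exact permutation test over all assignments of 5 against 5 samples.

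A total of 43 gene lists were fixed from textbook knowledge of the tissue, the disease model and the compound, including markers of tissues and cells a dissection could carry along. The 40 with at least 5 tested genes were tested with fry from limma 3.58.1 on voom log2 counts, with Benjamini-Hochberg adjustment over the 40. The fry test asks whether the genes of a list move, on balance, in 1 direction, and does not compare the list with other genes. It called 11 lists, 3 up and 8 down, and its test for change in either direction called 24. At an unadjusted p below 0.05 fry counted 22 lists. Camera with a preset correlation of 0.01 called 23 lists, all 11 among them, and with an estimated correlation 0, at which none of the 11 calls holds. A list mean is the mean log2 CPM over its tested genes.

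The rule for named genes took the 10 most raised and the 10 most lowered genes by log2 fold change among those past the threshold with a mean of at least 1 CPM and a symbol that is not a predicted model. It added the 4 tested members of smallest p of each described list, and 18 index genes, among them Il17a, Ifng, Tnf, Il1b, Il6, Csf2, Foxp3, Cd4, Cd3e, Aif1, Gfap, Mbp, Mog, Cyp1a1, Hmox1, Nfe2l2 and Cldn5. The grouping, the tests, the lists, this rule and the alternatives not named as later additions were set before the data were examined. Which 20 lists were described by gene was chosen after the list results were seen, as were the members named from other lists (Srebf2, C1ql1, Jchain, Nkg7, Car3 and Atf3). Some genes that the rule selects are not reported here and were left out of the search for outlying samples, whatever their values.

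The fitting steps were tested on simulated data for the comparison of Nar and EAE, with negative binomial counts for 14595 genes drawn from the means, dispersions and totals of these samples. With 200 genes changed, edgeR called 53 of 100 changed by 0.5 on the log2 scale and 91 of 100 changed by 1, with 11 false calls among 155. Changes of about 0.5 are therefore missed in close to 50% of genes at this depth and spread. Fry called 10 of 10 simulated lists raised by 0.5 and 1 of 20 unchanged lists. The simulated genes were drawn independently, while members of many real lists were correlated (camera estimate 0.481 for cholesterol synthesis genes and 0.589 for T cell markers). The fry result of the simulation does not carry over to such lists.

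Alternatives were DESeq2 size factors, upper quartile factors, no filter on low counts, a mean of at least 1 CPM, the DESeq2 1.42.0 Wald test, limma-voom with and without sample weights, the replicate number as a block, limma-trend on log2 of the authors' FPKM with 1 or 0.1 added (mean FPKM of at least 0.5, or no filter), other thresholds, camera with either correlation, an exact permutation test of list means, and leaving out each sample in turn. Thinning every sample to the lowest total and using the mitochondrial share as a covariate were added after the data were seen. So were enrichment of the GO identifiers in the deposited table among called genes (hypergeometric test, terms of 10 to 500 tested genes) and the weight given to the values without Nar 4.

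Some genes share exon bases with another annotated gene. Of genes that share at least 50% of their exon bases, 55.3% had at most 10 reads over all samples, against 28.8% of genes that share none and 7.40% of the 5876 that share a smaller part. Among list members, Mt2 had 5 reads and S100a4 and Pmp2 had 0, with 51.7% to 86.9% of their exon bases shared, while Mt1, which shares none, had 48493. Cfd and Ccl19 also share none and had 0 reads. Whether overlap lowered any count was not tested, and no strand setting is stated.

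Gene positions and overlaps were read with rtracklayer 1.62.0 and GenomicRanges 1.54.1, transcript GC content with Biostrings 2.70.1, and plots were drawn with matplotlib 3.10.9.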

Results

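Spinal cord of mice with experimental autoimmune encephalomyelitis (EAE) was profiled by RNA sequencing at day 14. EAE is a mouse model of multiple sclerosis in which immune cells enter the central nervous system and attack myelin, the lipid-rich sheath of axons. The 10 samples form 2 groups of 5, called Nar and EAE after the sample titles. Nar stands for mice given naringenin, a flavonoid of citrus fruit. The titles give this grouping, but the treatment field names naringenin for all 10 samples, so what the EAE group received is not known here. Spinal cord of mice without EAE was not analysed here. The labels do not say that the 5 samples of a group are 5 separate animals, so p-values measure the spread between these samples, which may be technical.

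The total count per sample was 14504726 to 15139706 reads in Nar (mean 14.8 ± 0.258 M, SD, n = 5) and 16658798 to 18961501 in EAE (17.8 ± 0.882 M, SD, n = 5). The difference of −2.95 M reads had a two-sided exact permutation p of 0.0079, the smallest that 5 against 5 samples allow. Reads of the mitochondrial genome made up 7.04 ± 0.401% of counts in Nar and 5.69 ± 0.893% in EAE (SD, n = 5 each, two-sided exact permutation p = 0.032). Whether the groups were prepared or sequenced apart is not known here, and such a difference could not be told apart from treatment. Genes with at least 1 read numbered 16553 to 16711 per Nar sample and 16755 to 16903 per EAE sample. Samples of a group differed by more than counting noise: the chi-square over its degrees of freedom was 4.14 to 18.2 between Nar samples and 6.64 to 39.5 between EAE samples.

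The comparison of the groups asks how naringenin treatment changes gene expression in the spinal cord of EAE mice. Genes of cholesterol synthesis and of myelin were higher in Nar, among them Lss, an enzyme of cholesterol synthesis (75.6 ± 7.04 against 43.4 ± 5.0 counts per M reads, CPM, SD, n = 5 each), and Ugt8a, an enzyme of myelin lipid synthesis (386 ± 26.6 against 240 ± 21.7 CPM). Fibroblast and meningeal matrix genes and disease-associated microglia genes were lower, among them Col1a1, a fibrillar collagen chain (7.15 ± 0.738 against 27.1 ± 2.95 CPM), and Apoe, the apolipoprotein that carries cholesterol between cells of the nervous system (2219 ± 101 against 5661 ± 992 CPM). Genes of T cells, macrophages, chemokines and reactive astrocytes had lower list means in Nar 1, 2, 3 and 5 than in every EAE sample, while sample Nar 4 lay within or above the EAE range.

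Of 14595 genes tested with edgeR's quasi-likelihood test, 574 passed an adjusted p of 0.05 (Benjamini-Hochberg), 230 higher and 344 lower in Nar. Beyond a fold change of 2, 7 of these genes were higher and 94 lower. The median log2 fold change was 0.39 among the genes called higher and −0.60 among those called lower. The 2 groups did not overlap in 845 genes, 5.79% of those tested against 0.794% expected by chance, and 437 of these were among the 574. Leaving out Nar 4 raised the count to 1486 (384 higher, 1102 lower), which held 572 of the 574. The count was 916 without EAE 3, 161 without Nar 1, 166 without Nar 5, 205 without Nar 3, 276 without EAE 1, 311 without EAE 4 and 325 without EAE 5. With the mitochondrial share of each sample as a covariate, an alternative chosen after seeing the data, 197 genes were called, 129 higher and 68 lower, of which 93 were among the 574.

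On the first principal component of log2 CPM, which held 45.8% of the variance, Nar 1, 2, 3 and 5 scored −35.2 to −24.6 and the EAE samples 8.17 to 34.9. Nar 4 scored 16.1, within the range of the EAE samples, and its mean correlation across genes was 0.982 with the EAE samples and 0.974 with the other Nar samples. For this reason the position of Nar 4 is given beside the inflammatory gene groups, though it did not lie with EAE in all of them. Each sample was left out in turn as planned, but the weight on Nar 4 came after its position was seen. Removing the Nar sample nearest EAE in these genes lowers their p-values. Values without Nar 4 thus describe the other samples and are no independent test.

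**Figure D1:**
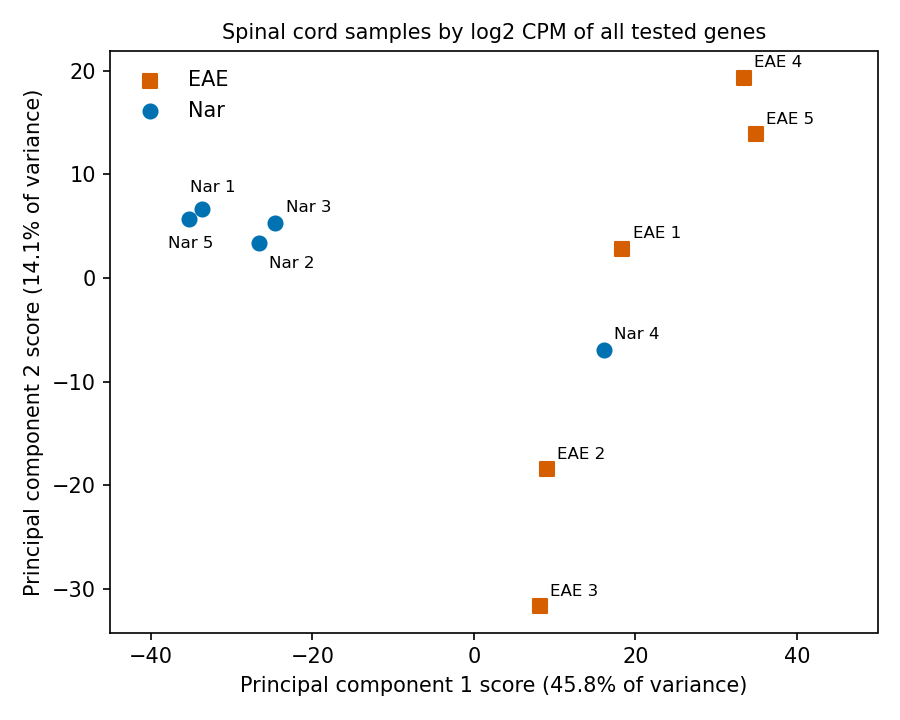
Scores of the 10 spinal cord samples on the first (x axis, 45.8% of variance) and second (y axis, 14.1% of variance) principal components of log2 CPM of all tested genes, with Nar samples as circles and EAE samples as squares. Nar 4 lies at 16.1 on the first component, among the EAE samples, and the other Nar samples lie at −24.6 or lower.

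Cholesterol synthesis was the gene list with the most members changed. All 20 of its genes were tested, and 18 rose in Nar over all genes tested, also 18 adjusted over the list alone, while 0 fell. The median log2 fold change was 0.60. Hmgcs1, which makes the HMG-CoA that the pathway starts from, had 446 ± 20.7 CPM in Nar and 231 ± 56.7 in EAE (log2 fold change 0.95, SE 0.147, edgeR adjusted p = 0.00709). Lanosterol synthase Lss (0.80, SE 0.0862, edgeR adjusted p = 0.0005), lanosterol demethylase Cyp51 (0.76, SE 0.0917, edgeR adjusted p = 0.00123) and sterol desaturase Sc5d (0.56, SE 0.0647, edgeR adjusted p = 0.000783) rose as well, and all 4 of these genes kept their calls without any single sample. Srebf2, the transcription factor that drives the pathway, rose by 0.32 (edgeR adjusted p = 0.00946). It is named here after its value was seen. The list passed limma's fry test (adjusted p = 0.000872), with camera adjusted p = 0.148 with an estimated correlation. Nar 4 shared this change: its list mean was 6.20 log2 CPM, against 6.23 to 6.31 in the other Nar samples and 5.35 to 5.81 in EAE.

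Hmgcs1 (ENSMUSG00000093930) lies on chromosome 13 from 119690379 to 119708260 in the GRCm38 coordinates of the files. Col1a1 (ENSMUSG00000001506) lies on chromosome 11 from 94936224 to 94953042, and Col3a1 (ENSMUSG00000026043) on chromosome 1 from 45311538 to 45349706. Gpnmb (ENSMUSG00000029816) lies on chromosome 6 from 49036546 to 49070929. Each interval is the whole annotated gene, with its exons and introns.

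**Figure D2:**
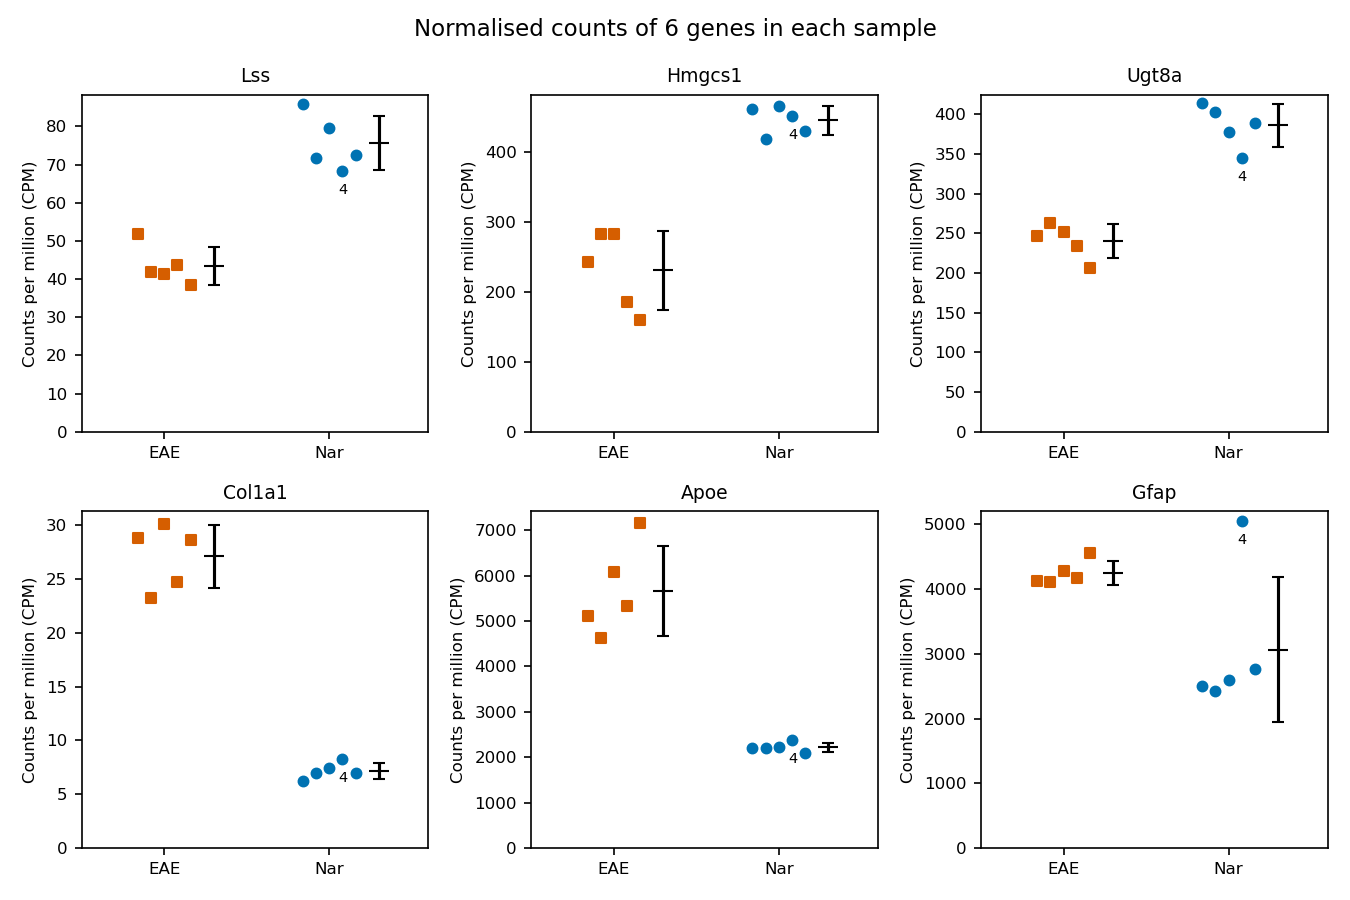
Normalised counts (y axis, CPM from 0) of Lss, Hmgcs1, Ugt8a, Col1a1, Apoe and Gfap in the 5 EAE samples (squares) and 5 Nar samples (circles), with the group mean and SD as a bar at the side and Nar 4 marked "4". Nar 4 lies with the other Nar samples in the first 5 genes, while in Gfap, which did not pass the test over all samples (edgeR adjusted p = 0.184), it lies apart from them.

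Myelin and mature oligodendrocyte genes rose in Nar. Of 16 tested, 6 rose over all genes tested and 7 adjusted over the list alone, with 0 falling and a median log2 fold change of 0.26. Ugt8a rose by 0.69 (SE 0.0718, edgeR adjusted p = 0.000437), Fa2h, the hydroxylase of myelin fatty acids, by 0.59 (SE 0.105, edgeR adjusted p = 0.0101), the myelin protein gene Mal by 0.37 (SE 0.0534, edgeR adjusted p = 0.00283) and Mobp by 0.34 (SE 0.0597, edgeR adjusted p = 0.00913). Without Nar 1 Fa2h (edgeR adjusted p = 0.0507) and Mobp (0.0551) lost their calls, Mobp also without Nar 5 (0.0562). The myelin protein genes Mog and Mbp did not pass: Mog was 0.37 higher (edgeR adjusted p = 0.0597, or 0.0231 without Nar 4) and Mbp 0.27 higher (edgeR adjusted p = 0.210). Fry called the list (adjusted p = 0.0104), with camera adjusted p = 0.296 with an estimated correlation, and the call ended without Nar 1 (fry adjusted p = 0.0504) or Nar 5 (0.0525). The list mean of Nar 4, 9.25 log2 CPM, lay above the EAE range of 8.81 to 9.16. Oligodendrocyte precursor genes did not pass (14 tested, 1 rose, C1ql1, fry adjusted p = 0.994), and their median (0.01), mean (−0.05) and test direction (up) differed in sign.

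Mitochondrially encoded genes rose, along with the higher mitochondrial read share of the Nar samples given above. Of 12 tested, 2 rose over all genes tested and 6 adjusted over the list alone. These 2 code for subunits of respiratory complex I, mt-Nd5 (0.43, SE 0.0717, edgeR adjusted p = 0.00677) and mt-Nd4l (1.04, SE 0.243, edgeR adjusted p = 0.0334). Few reads were counted for mt-Nd4l (4.09 CPM in Nar, 1.99 in EAE), and 2.36% of its exon bases are shared with another gene. Whether read assignment lowered its count was not tested, so its count need not reflect its abundance. Fry gave the list an adjusted p of 0.0391, with camera adjusted p = 0.296 with an estimated correlation, and the call ended without Nar 1, 2, 3 or 5 or EAE 1, 4 or 5 (fry adjusted p 0.0663 to 0.0902). Respiratory chain genes of the nucleus had a median of 0.43 but did not pass (21 tested, 0 rose, fry adjusted p = 0.159, 0.0317 without EAE 3).

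Fibroblast and meningeal matrix genes fell in Nar on balance. Of 12 tested, 8 were lower and 4 higher, the latter by at most 0.31. Over all genes tested 5 fell and 0 rose, and 5 fell adjusted over the list alone, with a median log2 fold change of −0.49. The fibrillar collagen genes Col3a1 (−2.72, SE 0.155, edgeR adjusted p = 6.46e-07) and Col1a1 (−1.92, SE 0.104, edgeR adjusted p = 6.46e-07) had the smallest p-values of all genes tested. The collagen-binding proteoglycan genes Lum (−1.34, SE 0.231, edgeR adjusted p = 0.00772) and Dcn (−1.0, SE 0.176, edgeR adjusted p = 0.0102) fell too, and these 4 genes kept their calls without any single sample. Fry called the list (adjusted p = 0.00138), with camera adjusted p = 0.192 with an estimated correlation. In this list Nar 4 lay with its group, at a mean of 3.23 log2 CPM against 3.01 to 3.15 in the other Nar samples and 3.59 to 3.96 in EAE.

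Disease-associated microglia genes, which microglia raise around lesions and debris, fell in Nar. Of 18 tested, 7 fell over all genes tested and 14 adjusted over the list alone, with a median of −0.95. Apoe fell by 1.35 (SE 0.101, edgeR adjusted p = 1.44e-05), Spp1, which codes for osteopontin, by 0.84 (SE 0.149, edgeR adjusted p = 0.0142), the lysosomal protease gene Ctsb by 0.58 (SE 0.122, edgeR adjusted p = 0.0232) and Gpnmb, a glycoprotein of phagocytic cells, by 3.80 (SE 0.737, edgeR adjusted p = 0.0306). Gpnmb lost its call without Nar 1, 3 or 5 or EAE 1, 4 or 5 (edgeR adjusted p 0.057 to 0.0818), and Ctsb without Nar 1, 3 or 5 or EAE 4 or 5 (0.0569 to 0.0655). Fry called the list (adjusted p = 0.00904), with camera adjusted p = 0.196 with an estimated correlation. Nar 4 lay apart, with a list mean of 6.11 log2 CPM against 4.62 to 4.88 in the other Nar samples and 6.17 to 6.68 in EAE. Apoe did not follow this, with 2372 CPM in Nar 4 against means of 2219 in Nar and 5661 in EAE. Spp1 changed little without Nar 4 (log2 fold change −0.88). Which cells the change in each gene came from was not tested. Without Nar 4, 17 of the 18 genes fell (fry adjusted p = 0.000143).

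Complement genes fell (12 tested, 1 fell over all genes tested and 8 adjusted over the list alone, fry adjusted p = 0.0177, camera adjusted p = 0.278 with an estimated correlation). The 1 gene was C3, the central component of the cascade, at 108 ± 54.5 CPM in Nar and 345 ± 32.4 in EAE (−1.68, SE 0.290, edgeR adjusted p = 0.0183), a call that ended without Nar 3 or 5 or EAE 4 (0.0534 to 0.0537). The list call ended without Nar 1 (fry adjusted p = 0.0504), Nar 2 (0.0536) or Nar 5 (0.0525). MHC class II antigen presentation genes passed fry at adjusted p = 0.0461 with a median of −1.10, but 0 of 14 fell over all genes tested and 1 adjusted over the list alone. Th1 and Th17 genes, those of the helper T cells that drive EAE, also passed fry at adjusted p = 0.0461, with 0 of 6 falling over all genes tested and 2 adjusted over the list alone. Only 6 of the 16 genes of the Th1 and Th17 list were tested, and Ifng, Tbx21, Il17a, Il17f and Csf2 were not among them. Both lists had camera adjusted p = 0.296 with an estimated correlation. The MHC class II call ended without any 1 of Nar 1, 2, 3 and 5 and EAE 1, 2, 4 and 5 (fry adjusted p 0.055 to 0.0962), and the Th1 and Th17 call without Nar 1, 2, 3 or 5 or EAE 1, 4 or 5 (0.0729 to 0.105). By exact permutation of list means the calls of all 3 lists ended (adjusted p = 0.0747 each). With the replicate number as a block the MHC class II call ended as well (fry adjusted p = 0.0906). Nar 4 lay inside the EAE range in all 3 lists, for example at 3.50 log2 CPM for MHC class II against 1.10 to 2.33 in the other Nar samples and 2.93 to 3.94 in EAE. Without Nar 4 the 3 lists had fry adjusted p of 0.000398, 0.00405 and 0.0172.

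Astrocyte identity markers fell by a small amount. Of 14 tested, 4 fell over all genes tested and 4 adjusted over the list alone, with a median of −0.15. They were the astrocyte transcription factor gene Sox9 (−0.43, SE 0.0899, edgeR adjusted p = 0.0202), the membrane protein gene Mlc1 (−0.29, SE 0.072, edgeR adjusted p = 0.0383), the water channel gene Aqp4 (−0.38, SE 0.0929, edgeR adjusted p = 0.0398) and the glutamate transporter gene Slc1a2 (−0.33, SE 0.0843, edgeR adjusted p = 0.0443). Each lost its call without single samples, Sox9 without Nar 1, 3 or 5 (edgeR adjusted p 0.0514 to 0.0575) and the others without 6 or 7 of the 10 (0.0519 to 0.113), and Slc1a2 also with the replicate number as a block (0.0886). Fry called the list (adjusted p = 0.0101), with camera adjusted p = 0.192 with an estimated correlation. Reactive astrocyte genes did not pass (21 tested, 2 fell over all genes tested and 3 adjusted over the list alone, fry adjusted p = 0.0592). The 2 over all genes were the adhesion receptor gene Cd44 (−0.93, edgeR adjusted p = 0.0465) and the membrane protein gene Emp1 (−0.70, edgeR adjusted p = 0.0469), which both lost their calls without any 1 sample other than Nar 4 (0.0601 to 0.123). Nar 4 lay at 5.60 log2 CPM in them, against 3.44 to 3.77 in the other Nar samples and 4.79 to 5.60 in EAE, and without Nar 4, 15 of 21 fell (fry adjusted p = 0.000565). The intermediate filament gene Gfap had a log2 fold change of −0.47 (edgeR adjusted p = 0.184), and −0.73 without Nar 4 (edgeR adjusted p = 4.01e-06).

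**Figure D3:**
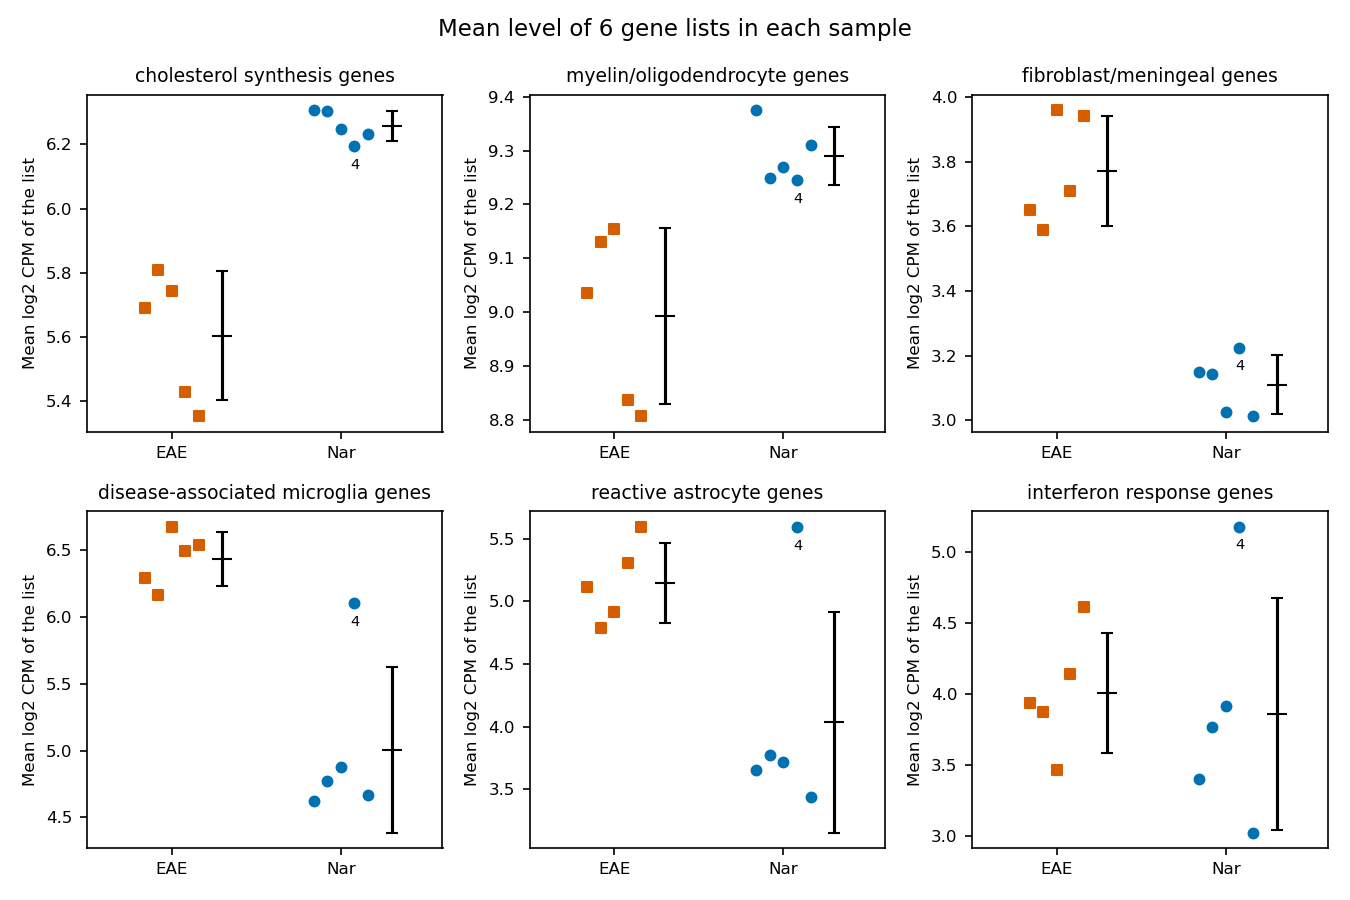
Mean log2 CPM over the genes of 6 lists (y axis, scaled to each list) in the 5 EAE samples (squares) and the 5 Nar samples (circles), with the group mean and SD as a bar at the side and Nar 4 marked "4". Nar 4 lies near the other Nar samples in the cholesterol, myelin and fibroblast lists and apart from them in the microglia, reactive astrocyte and interferon lists.

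PPAR and fatty acid oxidation genes fell (16 tested, 2 fell over all genes tested and 4 adjusted over the list alone, fry adjusted p = 0.00413, camera adjusted p = 0.148 with an estimated correlation). The call ended by exact permutation of list means (adjusted p = 0.0747) and with the replicate number as a block (fry adjusted p = 0.0507). The 2 were Cpt1a, which admits fatty acids to mitochondria (−0.32, SE 0.0607, edgeR adjusted p = 0.0128), and the lipid droplet protein gene Plin2 (−0.70, SE 0.145, edgeR adjusted p = 0.021). Plin2 had a log2 fold change of −0.87 without Nar 4 (edgeR adjusted p = 6.44e-05) and lost its call without Nar 1, 3 or 5 (edgeR adjusted p 0.0578 to 0.0647). Nar 4 lay with EAE in this list, at a mean of 3.94 log2 CPM against 3.53 to 3.71 in the other Nar samples and 3.88 to 4.20 in EAE. LXR targets did not pass as a list (10 tested, fry adjusted p = 0.0599, median −0.12), with 2 rising and 2 falling over all genes tested and 3 rising and 4 falling adjusted over the list alone. The desaturase genes Scd1 (0.49, edgeR adjusted p = 0.00171) and Scd2 (0.20, edgeR adjusted p = 0.0443, lost without any 1 of 8 of the 10 samples, 0.0653 to 0.179) rose. The cholesterol exporter gene Abca1 (−1.32, edgeR adjusted p = 0.00372) and the lipogenic transcription factor gene Srebf1 (−0.39, edgeR adjusted p = 0.00153) fell. Fry called the LXR list without Nar 1 (adjusted p = 0.032), Nar 3 (0.0471), Nar 4 (0.0172) or EAE 3 (0.0214), and Nar 4 again lay in the EAE range (6.60, against 6.36 to 6.48 in the other Nar samples and 6.58 to 6.71 in EAE).

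Targets of the aryl hydrocarbon receptor, a sensor of plant compounds among others, passed fry at adjusted p = 0.0461 with a median of −0.47 and camera adjusted p = 0.296 with an estimated correlation. Yet 0 of 5 fell over all genes tested and 1 adjusted over the list alone, and the call ended without Nar 1, 2, 3 or 5 or EAE 1 or 4 (fry adjusted p 0.0663 to 0.0951). Its best known target Cyp1a1 had 10 reads in all Nar samples together and 15 in EAE, too few to test. NRF2 antioxidant genes did not pass (14 tested, 0 fell over all genes tested and 2 adjusted over the list alone, fry adjusted p = 0.0985). Nfe2l2, which codes for NRF2, fell by 0.52 (SE 0.113, edgeR adjusted p = 0.0246, lost without Nar 1, 3 or 5 or EAE 1 or 4, 0.0594 to 0.0709), and its target Hmox1 was at −1.13 (edgeR adjusted p = 0.0597, or 2.27e-05 without Nar 4).

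T cell markers did not pass (10 tested, median −1.13, 1 fell over all genes tested, 1 rose and 5 fell adjusted over the list alone, fry adjusted p = 0.0599). The T cell receptor complex gene Cd3g fell by 2.47 (edgeR adjusted p = 0.0407), and Cd4 was at −1.82 (edgeR adjusted p = 0.152), or at −3.58 and −3.05 without Nar 4 (edgeR adjusted p = 0.000713 and 0.00442). Monocyte and macrophage markers did not pass (17 tested, 4 fell over all genes tested and 6 adjusted over the list alone, fry adjusted p = 0.0658). The 4 were Ms4a7, Lyz2, the lysosomal gene Cd68 (−1.83, edgeR adjusted p = 0.0255) and the endotoxin co-receptor gene Cd14 (−1.36, edgeR adjusted p = 0.0463). Homeostatic microglia markers did not pass either (14 tested, 3 fell over all genes tested and 5 adjusted over the list alone, fry adjusted p = 0.0674); the 3 were the matricellular protein gene Sparc (−0.41, edgeR adjusted p = 0.0162) and the receptor genes Gpr34 (−0.86, edgeR adjusted p = 0.0255) and P2ry13 (−0.86, edgeR adjusted p = 0.0463). Of 13 chemokine genes 1 fell over all genes tested and 1 adjusted over the list alone, Ccl3 (−2.36, edgeR adjusted p = 0.0499), with fry adjusted p = 0.0658. Inflammatory cytokine and NF-kB genes had 1 of 17 falling over all genes tested, the inflammasome sensor gene Nlrp3 (−1.74, edgeR adjusted p = 0.0235), with 1 rising and 10 falling adjusted over the list alone and fry adjusted p = 0.0515. The cytokine genes Tnf (−1.69, edgeR adjusted p = 0.111) and Il1b (−0.77, edgeR adjusted p = 0.681) and the microglial gene Aif1 (−0.56, edgeR adjusted p = 0.479) did not pass with all samples, but did without Nar 4 (Tnf −2.71, edgeR adjusted p = 0.0034; Il1b −2.78, 0.0304; Aif1 −1.27, 5.49e-05). Each gene called in these 5 lists lost its call without at least 1 sample (edgeR adjusted p up to 0.135).

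In these 5 lists Nar 4 was the highest Nar sample, with 3.45 log2 CPM for chemokines against 0.399 to 1.38 in the other Nar samples and 2.38 to 3.16 in EAE. Without Nar 4 fry called all 5 of them: T cell markers (adjusted p = 0.0134), monocyte and macrophage markers (0.00784), homeostatic microglia markers (3.92e-05), chemokines (0.000652) and inflammatory cytokines (0.00135). T cell markers were also called without EAE 3 (fry adjusted p = 0.034). Regulatory T cell genes (7 tested, 1 fell over all genes tested and 3 adjusted over the list alone, fry adjusted p = 0.0674) were called without Nar 4 (0.0172) or EAE 3 (0.0291). MHC class I genes (14 tested, 0 fell, 0 adjusted over the list alone, fry adjusted p = 0.346) were called without Nar 4 (0.0237). Nar 4 lay in the EAE range for regulatory T cell genes (2.30 log2 CPM, EAE 2.04 to 2.76). It lay above that range for MHC class I genes (5.81, EAE 5.03 to 5.62). Interferon response genes did not pass with or without Nar 4 (24 tested, fry adjusted p = 0.845, or 0.176 without it). With all samples 0 changed, also 0 adjusted over the list alone, with a median of −0.05, a mean of 0.03 and a test direction of down. Without Nar 4, 2 fell over all genes tested and the median was −0.44. Fry called 11 of 40 lists with all samples and 22 without Nar 4, which held all 11. The gain follows at least in part from the choice of Nar 4 by its values in such genes.

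Several index genes of EAE were too scarce to test. Over the 5 Nar and the 5 EAE samples together, Il17a had 2 and 2 reads, Ifng 3 and 7, Il6 12 and 33, Csf2 0 and 5, Foxp3 25 and 44 and Cd3e 29 and 76. Differences in the cytokine genes of helper T cells were thus not detectable at this depth. The tight junction gene Cldn5 did not pass (0.28, edgeR adjusted p = 0.121).

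The 10 genes that rose most by fold change mostly had few reads. Among them were Slc17a7, a vesicular glutamate transporter (1.90, SE 0.444, edgeR adjusted p = 0.036, with overlapping groups), the phospholipase gene Pla2g4b (1.71, with 66.5% of its exon bases shared with another gene), Amh, the anti-Müllerian hormone (1.36), the replication factor gene Mcm10 (1.19), the receptor accessory protein gene Ramp3 (1.06), mt-Nd4l, Hmgcs1, Stac3, a calcium channel adaptor of muscle (0.93), and the metalloprotease gene Adam21 (0.90). Leaving out Hmgcs1, their Nar means were 1.65 CPM (Pla2g4b) to 4.22 CPM (Slc17a7), and 8 of the 10 lost their calls without at least 1 sample, the exceptions being Amh and Hmgcs1.

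The 10 genes that fell most were Atp6v0d2, a subunit of the lysosomal proton pump, Gpnmb, the CD200 receptor family gene Cd200r4 (−3.76, SE 0.571, edgeR adjusted p = 0.00372), the macrophage gene Ms4a7 (−3.29, SE 0.60, edgeR adjusted p = 0.0129), lysozyme Lyz2 (−3.29, SE 0.675, edgeR adjusted p = 0.0362), the macrophage elastase gene Mmp12 (−3.27), the inhibitory lectin gene Cd22 (−3.11), the immune receptor gene Slamf7 (−2.98) and the myeloid receptor genes Lilrb4a (−3.02) and Lilr4b (−2.94). Atp6v0d2 had 0.054 ± 0.121 CPM in Nar, all of it in Nar 4, and 2.60 ± 1.74 in EAE (edgeR adjusted p = 0.00551). Lyz2 fell from 323 ± 139 CPM in EAE to 32.9 ± 36.9 in Nar. The size of these changes hangs on Nar 4: without it Atp6v0d2 had 0 reads in Nar, so that its fold has no upper limit, and the other log2 fold changes were −5.20 (Mmp12), −5.09 (Gpnmb), −4.95 (Ms4a7), −4.68 (Cd200r4), −4.44 (Slamf7), −4.30 (Cd22), −4.29 (Lyz2), −3.91 (Lilrb4a) and −3.72 (Lilr4b). Lilrb4a and Lilr4b are neighbouring genes of similar sequence, so reads may be split between them. Of the 10, Atp6v0d2 and Cd200r4 kept their calls without any single sample, Ms4a7 lost its call without Nar 1 (edgeR adjusted p = 0.0502), and Lyz2 without any 1 of Nar 1, 3 and 5 and EAE 1, 2, 4 and 5 (0.0509 to 0.102). Of the 59 called genes among the 106 followed by name, 21 kept their calls without any single sample.

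Markers of other tissues and cell types did not pass with all samples, though some did under other settings. By fry adjusted p these were neutrophil markers (5 tested, 0.183), Schwann cell and peripheral nerve genes (8 tested, 0.0849, or 0.0486 without Nar 4, 0.0464 without EAE 3, 0.0315 with the replicate number as a block and 0.0459 without a filter), sensory ganglion neuron genes (6 tested, 0.0777, or 0.0455 with that block), skeletal muscle genes (5 tested, 0.159) and erythroid genes (7 tested, 0.104, or 0.017 without EAE 2). B cell and plasma cell markers, NK cell genes and adipocyte genes had 3, 3 and 1 genes tested, too few for a list test. Among them the immunoglobulin joining chain gene Jchain fell by 2.86 (edgeR adjusted p = 0.0179) and the cytotoxic granule gene Nkg7 by 1.73 (edgeR adjusted p = 0.0383), while the adipocyte gene Car3 did not pass (0.39, edgeR adjusted p = 0.410). Adjusted over the list alone, 0 genes changed in the sensory ganglion and adipocyte lists, 1 rose in the muscle list and in the erythroid list, 1 fell in the neutrophil, B cell and NK cell lists, and 2 fell in the Schwann cell list.

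Neuronal and vascular lists did not pass the fry test. The adjusted p was 0.845 for pan-neuronal genes (14 tested, median 0.01), 0.159 for motor neuron genes (10 tested, median −0.32), 0.893 for synapse genes (16 tested, median 0.03, mean −0.05), 0.159 for endothelial and tight junction genes (14 tested) and 0.159 for vascular adhesion genes (9 tested). Adjusted over the list alone, 3 motor neuron genes and 2 vascular adhesion genes fell, and 0 changed in the other 3 lists. Over all genes tested the 1 to fall was Spp1, which is also in the microglia list.

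Lists of cell state did not pass the fry test either. Its adjusted p was 0.627 for ependymal genes (11 tested, median 0.12, mean −0.03, direction down), 0.963 for cell cycle genes (14 tested, median 0.10, mean 0.15, direction down), 0.956 for glucocorticoid response genes (11 tested), 0.844 for circadian clock genes (14 tested) and 0.828 for unfolded protein response genes (12 tested, median 0.01, mean −0.05, direction down). Immediate early and heat shock genes were at 0.0599 (14 tested, 1 fell over all genes tested, the stress-induced transcription factor gene Atf3 at −1.73, edgeR adjusted p = 0.0371, or −2.41 without Nar 4), or 0.00791 without Nar 4 and 0.0131 without EAE 5 by fry. Adjusted over the list alone, 1 ependymal gene and 2 immediate early genes fell, and 0 changed in the other lists.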

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

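The tests on sample Nar 4 were chosen after its position had been seen, and the dilution test of the cholesterol genes after the pan-neuronal result. The other tests in this part were set before their results were seen. A value is listed here when the highest or lowest of 5 samples lay far from the nearest other one relative to the range of its group (Dixon's test at 95%). Chance lists about 1 in 20 groups, or 14.8 of the 296 examined, and 36 were found. Of these, 26 were values of Nar 4, in all of which it was the highest Nar sample.

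By list mean (log2 CPM), Nar 4 stood above the other Nar samples for homeostatic microglia markers (6.03, next 5.12), disease-associated microglia genes (6.11, next 4.88), inflammatory cytokine and NF-kB genes (2.74, next 1.61), complement genes (5.62, next 4.07), reactive astrocyte genes (5.60, next 3.77) and cell cycle genes (3.19, next 1.87). By gene (log2 CPM), it was the highest Nar sample for the microglia and macrophage genes Atp6v0d2 (−1.35), Gpnmb (4.24), Cd68 (4.68), Cd14 (3.74), Aif1 (4.65), P2ry13 (4.67), Ctsb (10.2), Cd86 (3.16), Itgb2 (5.28) and C3ar1 (4.02). The same held for the inflammatory genes Il1b (2.82), Cxcl16 (3.69), Casp1 (2.93) and Tnfaip3 (3.22), for the astrocyte genes Gfap (12.3), Cd44 (5.60) and Cd109 (4.40), and for Nfe2l2 (5.92), Hmox1 (4.13) and Dcn (4.22).

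On genes called between the other 4 Nar and 4 EAE samples, Nar 4 was nearer the Nar mean in 35.0% on average (30.6% to 43.8%), against 16.1 ± 11.5% (SD, n = 5, 7.79% to 34.6%) for the EAE sample set aside each time; it was higher in all 5 gene sets but below the limit of 51.1% for a further EAE sample, so a wrong label cannot be told apart from a Nar sample with strong inflammation. The 2 measures tried before this one gave 41.2% and 20.2% for Nar 4 against 16.1% to 44.7% and 3.02% to 19.5% for EAE samples, on gene sets that differed between them, and did not decide it either. Other values run with the Nar label, as the list means of Nar 4 for cholesterol synthesis (6.20, EAE 5.35 to 5.81), fibroblast (3.23, EAE 3.59 to 3.96), myelin (9.25, EAE at most 9.16) and astrocyte identity genes (8.44, EAE at least 8.50) and its total of 14932736 reads (EAE at least 16658798) lay outside the EAE range on the Nar side. These lists were called with Nar 4 counted as Nar, so its place in them is no independent support for its label. RNA of these EAE animals mixed into a sample like the other Nar ones would leave inflammatory genes at or below the highest EAE sample. Yet 18 of 24 interferon response genes were highest in Nar 4 of all 10 samples (list mean 5.18 against at most 4.61 in EAE). The 2.4 expected by chance holds for independent genes only, and these were correlated (camera estimate 0.772). The values argue against such a mixture as the source of the interferon signal. EAE RNA in a sample with an interferon response of its own is not excluded. A difference in disease course between mice may also account for Nar 4 and was not tested. Nar 4 also had the lowest mean of caudal less rostral Hox genes of all 10 samples (−2.64 log2 units, against −1.69 to 0.67). Whether its spinal level differed was not tested.

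The higher cholesterol synthesis genes in Nar, which include Nar 4, were weighed against 3 technical explanations. A lower share of oligodendrocytes in EAE would lower the myelin list as much, but the cholesterol list mean less the myelin list mean was 0.355 log2 units higher in Nar (two-sided exact permutation p = 0.0079, n = 5 each). Dilution of cord RNA by infiltrating cells would lower pan-neuronal genes by about as much, but their list mean differed by 0.025. TMM scaling centres the bulk of genes (median log2 fold change 0.016 over all tested genes), so this value cannot show whether dilution occurred. It shows only that a dilution alike for all cord genes would not set cholesterol genes apart from pan-neuronal ones. GC content or length does not explain the median of 0.596, since the highest median of 10000 lists matched on both was 0.179. The myelin and matched-list tests argue against their explanations as the whole cause. The pan-neuronal test does so only for a dilution alike in all cord genes. A response of cord cells to treatment or to the state of the lesions may be the cause, as a hypothesis found on the same data, and the higher mitochondrial read share of Nar samples stays open.

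In the other samples, EAE 5 was the highest EAE sample for inflammatory cytokine and NF-kB genes (list mean 3.09, next 2.54) and for Il1b (3.10), and the lowest for Gpr34 (3.98) and Scd2 (11.4). EAE 4 was the highest EAE sample for Amh (0.247), Ms4a7 (2.11) and Cd3g (1.84), and the lowest for Cxcl12 (6.43). Nar 2 was the lowest Nar sample for ependymal and motile cilium genes (list mean 0.446, next 1.59) and Nar 5 for the T cell adaptor gene Lat (−1.61). All gene values here are log2 CPM. With 4 values each for EAE 5 and EAE 4 and 1 each for Nar 2 and Nar 5, these were together fewer than the 14.8 that chance lists over all groups examined. None of them need say anything about its sample.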

How the results depend on the processing

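Thinning to equal totals and the mitochondrial covariate were chosen after the data were seen; the other alternatives were planned. The 574 genes called by edgeR became 526 to 606 under other scalings or filters, 611 with counts thinned to the lowest total (33.7% higher in Nar, against 40.1%), and 538 to 729 by limma on FPKM (26.0% to 26.8% higher). The count moved by over 1.5 times with the DESeq2 Wald test (1308), limma-voom (881), voom with sample weights (2999), an adjusted p of 0.1 (1266), a log2 fold change over 1 as well (101, a subset by construction) and the mitochondrial share as covariate (197, of which 65.5% were higher). Without single samples it ranged from 161 (without Nar 1) to 1486 (without Nar 4). The cause of these moves was not tested. The 11 lists called by fry became 17 without a filter, 19 thinned, 23 by camera with its preset correlation, 0 with an estimated one (at an unadjusted fry p below 0.05 there were 22), 7 by exact permutation of list means, and 5 (without Nar 5) to 22 (without Nar 4) without single samples.

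With the replicate number as a block 636 genes were called (29.2% higher, 441 shared) and 12 lists. The numbers share no origin in the labels: same-number samples deviated with correlations of −0.227 to 0.161, and 0 of 5 Nar samples correlated best with their own number. Under the block MHC class II (fry adjusted p = 0.0906) and PPAR genes (0.0507) fell out, as did 8 of 59 named genes by edgeR, among them Slc17a7, mt-Nd4l, Stac3, Adam21, Ccl3, Slc1a2 and Scd2 (adjusted p 0.0511 to 0.0922), while Schwann cell (fry adjusted p = 0.0315), LXR (0.0315) and sensory ganglion lists (0.0455) were gained. Thinning ended the calls of Mcm10, Stac3 and Scd2 (edgeR adjusted p 0.0504 to 0.0664), and log2 FPKM that of Scd2 (limma adjusted p = 0.103). No filter ended the Th1 and Th17 call (fry adjusted p = 0.148) and gained T cell, cytokine and NF-kB, reactive astrocyte, Schwann cell, LXR and immediate early lists (0.0459 to 0.0476). Thinning gained T cell, regulatory T cell, monocyte, chemokine, cytokine and NF-kB, reactive astrocyte, LXR and immediate early lists (fry adjusted p 0.0185 to 0.049), and DESeq2 size factors the cytokine and LXR lists (0.0494 each). Exact permutation ended the calls of the Th1 and Th17, MHC class II, complement, PPAR and mitochondrially encoded lists and gained the Schwann cell list (adjusted p = 0.0454).

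Directions reversed only in lists and genes that did not pass, and the cause was not tested. For oligodendrocyte precursor genes the adjusted p was then 0.976 with DESeq2 size factors (fry), 0.913 without a filter (fry), 0.827 with the replicate block (fry), 0.884 thinned (fry), 0.846 and 0.937 by camera and 0.502 by exact permutation. Cell cycle genes reversed with the block (fry adjusted p = 0.858) and by exact permutation (0.929), and synapse genes when thinned (0.967) and by exact permutation (0.691). Without single samples, fry adjusted p ranged from 0.648 to 0.992 for oligodendrocyte precursor, 0.270 to 0.992 for cell cycle, 0.588 to 0.972 for synapse, 0.406 to 0.994 for pan-neuronal, 0.195 to 0.994 for circadian, 0.402 to 0.942 for ependymal, 0.176 to 0.994 for interferon response, 0.657 to 0.960 for glucocorticoid response and 0.458 to 0.951 for unfolded protein response genes, each with a reversal in at least 1. The log2 fold change ranged from −2.78 to 0.12 for Il1b (reversed without EAE 5), from −0.25 to 1.41 for Ifi27l2a and from −0.036 to 0.29 for Stat2 (both reversed without Nar 4). Depth limits genes of few reads, such as the cytokine genes of T cells.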

Other observations

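The enrichment of GO terms, the choice of the genes named in this part, the test with equal totals and the measures of Nar 4 were chosen after the results were seen; the tests of spinal level, of dorsal horn genes and of other splits were set before. The hypergeometric test of GO terms treats genes as independent draws and leaves out the spread between samples. Where genes change together its p-values can be far too small, so they describe the called genes only. By GO terms, extracellular matrix genes were lower in Nar, among them Col1a1, Col3a1, Lum and Dcn of the fibroblast and meningeal matrix list. Of the called genes that were lower, 26 belonged to the GO term for collagen-containing extracellular matrix, against 5.37 expected (hypergeometric test, adjusted p = 2.86e-08 over 7196 tests, 3598 terms in each direction). They included Postn, a matrix protein of wound healing (−2.44, edgeR adjusted p = 0.000437), Prelp (−0.71, edgeR adjusted p = 8.84e-05), the small proteoglycan gene Bgn (−0.69, edgeR adjusted p = 0.000783) and Col15a1 (−1.14, edgeR adjusted p = 0.000783), all of which passed without Nar 4 as well. Lysosomal genes were also over-represented among lower genes, at 23 against 8.28 expected (hypergeometric test, adjusted p = 0.0028). Among them were the protease gene Ctsa (−0.58, edgeR adjusted p = 0.00123), the lipid hydrolase gene Lipa (−0.49, edgeR adjusted p = 0.0171), the sphingolipid activator gene Psap (−0.27, edgeR adjusted p = 0.0136) and Hexa (−0.56, edgeR adjusted p = 0.0254). Nar 4 lay near EAE in some of them, with 57.1 CPM for Hexa (EAE 62.5 ± 7.23, SD, n = 5), and all 4 passed without it as well. Soat1, which esterifies cholesterol for storage, fell by 0.50 (edgeR adjusted p = 0.0015), while cholesterol synthesis genes rose.

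Of 5 genes looked up as ones that injured neurons raise, 1 is not reported here, so the other 4 do not give the share that fell. Sprr1a fell by 2.66 (edgeR adjusted p = 0.00141) and Atf3 by 1.73 (edgeR adjusted p = 0.0371, or by 2.41 without Nar 4, which had 6.48 CPM against 8.64 ± 1.19 in EAE, SD, n = 5). Gal (0.45, edgeR adjusted p = 0.245) and Sox11 (0.05, edgeR adjusted p = 0.882) did not pass. No list of such genes was tested, so a lower injury response as a whole is not shown.

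Of 230 genes called higher in Nar, 7 belonged to the GO term for neuropeptide signaling, of 73 in the term and against 1.16 expected (hypergeometric test, adjusted p = 0.0191). They were the precursor genes of enkephalin (Penk, 0.33, edgeR adjusted p = 0.0183), substance P (Tac1, 0.49, edgeR adjusted p = 0.0193), neuropeptide Y (Npy, 0.54, edgeR adjusted p = 0.0232), neurokinin B (Tac2, 0.60, edgeR adjusted p = 0.0464) and gastrin-releasing peptide (Grp, 0.63, edgeR adjusted p = 0.0383), the receptor gene Sstr2 (0.51, edgeR adjusted p = 0.0452) and Scg5 (0.23, edgeR adjusted p = 0.0494), while outside the term the cholecystokinin gene Cck also rose (0.56, edgeR adjusted p = 0.0172). These peptides are made by neurons of the dorsal horn, so more dorsal horn tissue in the Nar samples may be the cause, and 7 dorsal interneuron transcription factors had a median log2 fold change of 0.313, just past the 0.3 set for this explanation, with 1 of them, Gbx1, called. A different spinal level cannot be told apart: caudal less rostral Hox genes differed by −0.159 log2 units with an SE of 0.651 (two-sided exact permutation p = 0.833), while 8 of 9 rostral genes were higher in Nar, 1 of them called (Hoxb6, 0.37, SE 0.0726, edgeR adjusted p = 0.0157). Of the caudal genes, none called, Hoxa9 (0.18), Hoxd9 (0.33), Hoxa10 (0.58) and Hoxc10 (0.62) were also higher and Hoxb9 (−0.07) and Hoxc9 (−0.07) lower. A change within the same neurons was not tested.

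Other splits of the 10 samples were drawn to see how often such counts arise. Of 100 splits, 1, the real one, gave 574 genes or more, and the highest other gave 457, so such a count arose in under 5% of the splits drawn. For lists, 3 of 100 gave 11 or more, with 19 in the highest other, which is also under 5%. These 2 other splits exchanged Nar 4 with EAE 3 or EAE 2, while exchanging it with EAE 4 gave 0 genes and 0 lists and with EAE 1 gave 0 genes and 10 lists. The exchange with EAE 5 was not among the splits drawn. Since the samples may not be separate animals, splits of them cannot exclude a chance difference between animals or preparations. The greater read number of the EAE samples does not by itself account for the count of 574 genes, since 611 were called with equal totals. Thinning equalises read number only. With the mitochondrial share as a covariate 197 genes were called, 93 of them among the 574. A difference in preparation or sequencing between the groups therefore cannot be told apart from treatment.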
